A study of Mus musculus and Homo sapiens with 60 samples.

How the data were processed

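ChIP-seq for Myc (antibody N262), RNAPII, H3K4me3, H3K4me1 and H3K27ac was measured in mouse B cells, mouse lymph node tumours, mouse 3T9 fibroblasts and human P493-6 cells. Per the labels' protocols, spleen B cells came from C57BL/6 animals of 6 to 8 weeks and were enriched with B220 beads, tumour cells were pressed out of lymph nodes without further purification, and sonicated fragments averaged 250 bp. MycER was activated with 400 nM OHT for 4 h and compared with ethanol. Serum was withdrawn for 48 h and given back at 10% for 1 or 2 h. P493-6 cells had 0.2 µg/mL tetracycline (0 h), 200 nM OHT with tetracycline (low Myc) or no treatment (high Myc), and the 1 h and 24 h cells were released after 72 h of tetracycline.

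Reads were aligned with BWA 0.6.2, handled with SAMtools and called with MACS 1.4.1 on mm9 or hg19, per the submitters' processing notes, which name the tools without their settings. An input library of another series served for the P493-6 Myc and RNAPII lists, per the series' design text, and was not used here. Each sample had its own list of 5 columns, so peaks were called per library. The score in the deposited lists is the authors' own value for each peak, on the scale of -10 log10 of the MACS p-value, from 80.01 to 3233.06. It was used only to rank or filter peaks within a list. Peak numbers ran without gaps in 18 lists and with gaps in 35, and what removed the missing peaks is not given in the sources used here. The Eµ-myc Myc lists held 47.7% to 78.4% of their numbers (highest numbers 14635 in wild-type spleen, 26906, 8324 and 17670 in transgenic spleen and 39186, 38966 and 43569 in tumours), and the Eµ-myc RNAPII lists held 100%. The P493-6 high Myc sample carried the build mm9 in the notes, but its chromosome 1 peaks reached 249219825, past the highest end of 197068979 in the mouse lists, and it was treated as hg19. No 2 lists were identical (0 identical pairs). A start below 0, found in 6 peaks, was set to 0.

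Samples were grouped by the labels' genotype, cell type, treatment and antibody. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Marks of a stage were the merged peaks of its libraries. Serum samples were set against marks of the MycER 0 h cells and P493-6 samples against marks of the 24 h cells. Shuffled background came from 100 random placements on the same chromosome with a fixed seed of 20, chromosome lengths being the highest peak end over the lists of a build. Shares of single libraries have exact (Clopper-Pearson) 95% binomial intervals, with half-widths of at most 1.29 points in lists of 5000 peaks or more and 4.02 in smaller ones. These intervals cover counting error only. Read depth per sample is not known from peak lists, so a difference in peak number can also reflect depth or enrichment.

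Groups were compared with exact two-sided permutation tests. The p was first computed from absolute differences, which gave 0.0286 for the H3K4me3 peak number, and was changed to double the smaller tail after that value was known. By double the smaller tail, these exact comparisons cannot go below p = 0.1 with 3 against 3 libraries or below 0.0571 with 4 against 3, so none of them could pass 0.05, whereas by absolute differences 4 against 3 could. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples. Single-library models were compared without a test. The kind of test, the alternatives for the Myc, H3K4me3 and H3K4me1 results of the Eµ-myc model and for the single-library models (a score filter at each list's median, an overlap of 50% of the peak, equal numbers of highest-scoring peaks, chromosomes 1 to 19, covered length, other definitions of H3K4me3 and tumour-only regions, replicate numbers as pairs, leaving out each library) and the rule for naming regions were fixed before the data were examined. The definition of the two-sided p, peaks set to 500 bp, leaving out the 2 Myc libraries with narrow peaks, and all alternatives for RNAPII, H3K27ac, the wild-type marks at tumour-only regions and the sharing between fibroblasts and tumours were chosen later. The rule named the 5 tumour-only and 5 common regions with the highest mean score percentile over the tumours, and the 3 highest-scoring gained and shared peaks of each single-library model. Where scores were tied, as in the MycER model, the score alone did not decide which peaks were named. Regions are given by coordinates, since no gene annotation on mm9 or hg19 was used here, and the planned promoter gene lists and E-box motif counts were not analysed here for the same reason.

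Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The overlap code was tested on simulated data made from 3 real lists with a known share of overlapping peaks, which it recovered with an error of 0 points. It was also checked on 4 pairs of lists against bedtools 2.31.1, with equal counts in all 4.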

Results

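Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the transcription factor Myc in 4 models in which its level or activity was changed. RNA polymerase II (RNAPII) and 3 histone marks were mapped beside it. H3K4me3 is enriched at active promoters, H3K4me1 at enhancers and promoter flanks, and H3K27ac at active promoters and enhancers. The Eµ-myc mouse carries a Myc transgene driven by an immunoglobulin enhancer and develops B-cell lymphoma. Its samples were spleen B cells of wild-type animals, spleen B cells of transgenic animals and tumour cells from transgenic lymph nodes. Mouse 3T9 fibroblasts were studied with a Myc protein fused to a hormone-binding domain of the oestrogen receptor (MycER), which 4-hydroxytamoxifen (OHT) activates, and after serum was given back to starved cells. P493-6 is a human B-cell line with a Myc transgene that tetracycline represses. Of the 60 samples, 53 had a peak list (44 mouse, 9 human, 17 of them Myc), and the 7 inputs had none. Mouse coordinates are on mm9 and human coordinates on hg19, counted from 1.

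The first comparison asked how Myc binding differed between spleen B cells and tumours. Tumours had 29252, 27347 and 34142 Myc peaks, or 30247 ± 3505 (SD, n = 3). Transgenic spleen B cells had 12956, 5246 and 12985, or 10396 ± 4459.8 (SD, n = 3), and the 1 wild-type spleen library had 6978. The ratio of tumour to transgenic spleen was 3.14 (geometric means). Myc peaks covered 49.8 ± 5.55 Mb (SD, n = 3) in tumours, 10.9 ± 8.67 Mb (SD, n = 3) in transgenic spleen and 1.80 Mb in wild-type spleen. The peak number gave p = 0.1 in an exact two-sided permutation test of 3 against 3 libraries, the smallest p that the 20 assignments permit. Covered length gave a larger ratio of 5.70, and the peaks of wild-type library 1 and transgenic spleen library 1 were narrow (medians of 233 and 261 bp, against 1386 to 1476 bp in the other 5).

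Both promoter-like and distal Myc peaks were more numerous in tumours. Myc peaks on an H3K4me3 region of the same stage numbered 18612 ± 171 (SD, n = 3) in tumours and 7304 ± 2947 (SD, n = 3) in transgenic spleen, a ratio of 2.55. Myc peaks off H3K4me3 and on H3K4me1 numbered 10147 ± 3657 (SD, n = 3) in tumours and 2428 ± 1627 (SD, n = 3) in transgenic spleen, a ratio of 4.18. The share of Myc peaks on H3K4me3 was 80.7% in wild-type spleen, 71.3% ± 5.56 (SD, n = 3) in transgenic spleen and 62.1% ± 7.15 (SD, n = 3) in tumours. The difference between tumours and transgenic spleen of -9.21 points gave p = 0.2 in an exact permutation test of 3 against 3, and both numbers gave p = 0.1 in the same exact test. With an equal number of highest-scoring peaks per library the difference in share turned to 13.0 points (exact p = 0.2). It was -23.3 points on H3K4me3 regions present in every library of a stage and -25.3 on wild-type regions (exact p = 0.1 for each), and -5.22 without tumour 3.

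H3K4me3 regions carried Myc more often in tumours. A Myc peak lay on 65.3% ± 1.05 (SD, n = 3) of tumour H3K4me3 regions, 35.9% ± 12.4 (SD, n = 3) of those of transgenic spleen and 24.8% of those of wild-type spleen. Among H3K4me3 regions that also had RNAPII, 82.8% ± 1.16 (SD, n = 3) carried Myc in tumours, 56.1% ± 17.5 (SD, n = 3) in transgenic spleen and 40.7% in wild-type spleen. Among those without RNAPII the shares were 34.8% ± 2.396 (SD, n = 3), 14.5% ± 7.08 (SD, n = 3) and 9.85%. Tumour regions merged 3 H3K4me3 and 3 RNAPII lists, and those of each spleen genotype 2 and 1, so the region sets differed between stages. On wild-type regions with RNAPII, Myc lay on 90.3% to 94.8% in tumours and 35.4% to 67.2% in transgenic spleen. On wild-type regions without RNAPII the shares were 50.0% to 52.6% and 7.98% to 22.9%. The tumour minus transgenic spleen difference over all H3K4me3 regions was 29.3 points (exact permutation p = 0.1, n = 3 against 3, again the smallest possible). It was 46.8 points on H3K4me3 regions present in every library of a stage and 36.3 on wild-type regions. With an equal number of highest-scoring peaks, 5246 per library, it turned to -3.57 points (exact permutation p = 0.1). That cut caps the share that can be bound, and tumours had 26252 H3K4me3 regions against 17701 in transgenic spleen. The turn therefore cannot tell how often H3K4me3 regions carried Myc at each stage.

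**Figure D1:**
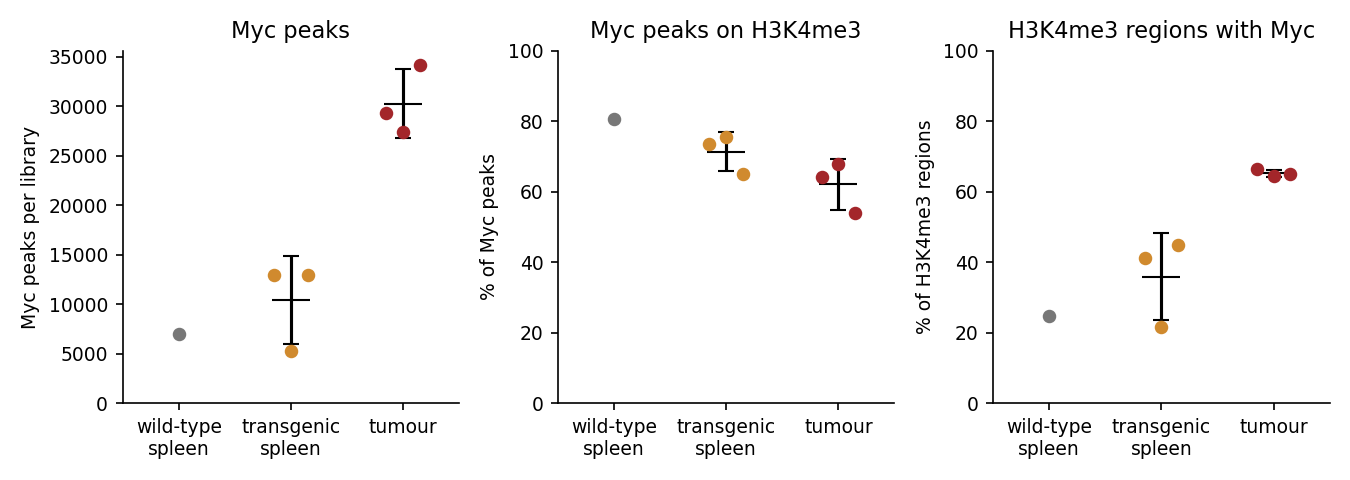
Myc peaks per library (left), percent of Myc peaks on H3K4me3 (middle) and percent of H3K4me3 regions with a Myc peak (right) in wild-type spleen, transgenic spleen and tumours. Points are libraries, bars show the mean and SD of 3 libraries, and tumours sit between 64.4% and 66.4% in the right panel against 21.7% to 44.9% in transgenic spleen.

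Most Myc sites of spleen B cells were also bound in tumours. Of the Myc peaks of a transgenic spleen library, 90.1% on average overlapped a peak of a tumour library (9 pairs, SD 7.00, range 79.98% to 98.6%). Of wild-type spleen peaks, 85.6% did (3 pairs, SD 0.979). Within a stage, 62.0% of transgenic spleen peaks were found in another transgenic spleen library (6 pairs, range 39.5% to 98.2%) and 65.9% of tumour peaks in another tumour (6 pairs). In the other direction, 28.0% of tumour peaks were found in a transgenic spleen library (9 pairs, range 14.2% to 44.2%). Within each tumour the peaks also found in spleen lay high in the deposited score, at median percentiles of 74.5, 72.3 and 73.6, and the peaks found in no spleen list at 28.8, 28.0 and 35.4. No test was made of these shares, since pairs of libraries are not independent, and a share found also depends on the length of the list searched.

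Merging the 7 Myc lists of the Eµ-myc model gave 48658 regions. A total of 4170 were tumour-only, that is, found in all 3 tumours and in none of the 4 spleen libraries, and 2618 were found in all 7. Tumour-only Myc regions mostly lay where wild-type spleen B cells already had a mark. Of them 85.3% overlapped wild-type H3K4me1, 75.4% H3K27ac, 51.0% H3K4me3 and 28.7% RNAPII, and 86.4% (exact 95% binomial interval 85.3 to 87.5) overlapped at least 1 of the 4, against 11.6% for shuffled positions. Regions bound in all 7 libraries overlapped these marks at 99.4%, 99.0%, 92.9% and 81.6%. In tumours, 65.6% of tumour-only regions had H3K4me3 and 58.9% had RNAPII. RNAPII was present in a tumour and absent from wild-type spleen at 1282 of these regions, H3K4me3 at 635 and H3K27ac at 494. The reverse held at 20, 28 and 43 regions. Tumour marks merged 3 lists each, and wild-type marks 1 list for RNAPII and H3K27ac and 2 for H3K4me3, which favours the first counts. Shuffled positions met RNAPII at 6.32% in tumours and 1.79% in wild-type spleen. The number of tumour-only regions was 2242 with peaks at or above the median score, 66 with an equal number of highest-scoring peaks and 10915 when 2 tumours were enough. It was 6753 without transgenic spleen library 3 and 7911 without tumour 3, where the rule asked for fewer libraries.

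**Figure D2:**
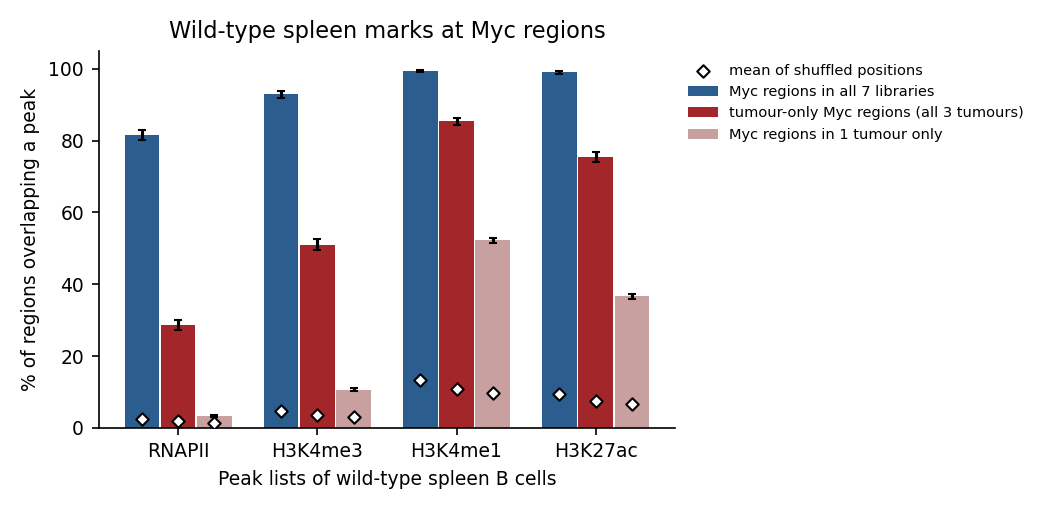
Percent of Myc regions overlapping each peak list of wild-type spleen B cells, for regions in all 7 Myc libraries (n = 2618), tumour-only regions (n = 4170) and regions in 1 tumour only (n = 21334). Error bars are exact 95% binomial intervals, diamonds are the means of 100 shuffles, and tumour-only regions reach 85.3% for H3K4me1 and 28.7% for RNAPII.

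Individual regions showed both kinds of site. The tumour-only region with the highest mean score percentile over the tumours (95.7) was chromosome 7, 28469326 to 28471094. It had none of the 4 marks in wild-type or transgenic spleen and all 4 in tumours, as did chromosome 7, 10723459 to 10725180 (90.7). Chromosome 14, 10221258 to 10223187 (92.6) and chromosome 4, 137461668 to 137467622 (91.9) had H3K4me1 and H3K27ac but neither H3K4me3 nor RNAPII in spleen, and all 4 in tumours. Chromosome 11, 5970562 to 5972638 (89.9) had H3K27ac in tumours and none of the other marks at any stage. The 5 highest regions bound in all 7 libraries had all 4 marks at every stage. These were chromosome 8, 73218452 to 73225942 (99.0), 74113934 to 74124273 (98.8) and 73286111 to 73295950 (98.7), chromosome X, 91457114 to 91459433 (98.7) and chromosome 10, 79726785 to 79729576 (98.7). When at least 50% of a region's length had to be overlapped, these 5 had a Myc peak in only 3 to 5 libraries.

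The next question was whether RNAPII and the marks differed between spleen and tumours. RNAPII peaks numbered 15571 in wild-type spleen, 17173 in transgenic spleen and 29159 ± 1999.8 (SD, n = 3) in tumours, a tumour to spleen ratio of 1.78 (geometric means, as for the other marks). H3K4me3 peaks numbered 20106 ± 1508 (SD, n = 3) in tumours and 17254.5 ± 876 (SD, n = 4) over wild-type and transgenic spleen, a ratio of 1.16. For H3K4me1 the numbers were 54405 ± 10164 (SD, n = 3) and 49127.5 ± 7210.3 (SD, n = 4), a ratio of 1.10. H3K27ac peaks numbered 40757 in wild-type spleen, 30895 in transgenic spleen and 35379 ± 6205 (SD, n = 3) in tumours, a ratio of 0.987. The exact two-sided permutation p was 0.0571 for H3K4me3, the smallest that 35 assignments of 4 against 3 permit, and 0.457 for H3K4me1. The H3K4me3 exact permutation p was 0.0286 by absolute differences, the definition computed first, and 0.229 for covered length. The H3K4me1 ratio was 0.996 without tumour 3, and the H3K27ac ratio 1.04 without tumour 1 and 1.03 without tumour 2. By covered length the RNAPII ratio was 3.29. RNAPII covered 68.5 and 65.0 Mb in tumours 2 and 3, whose peaks were wide (medians of 1432 and 1545 bp). It covered 22.3 Mb in tumour 1 (median of 581 bp), 17.9 Mb in wild-type and 11.1 Mb in transgenic spleen.

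Regions that gained RNAPII in tumours carried Myc less often than regions with RNAPII throughout. RNAPII was present in all 3 tumours and in neither spleen list at 2943 regions, of which 28.1% had Myc in all 3 tumours. Of the 8182 regions with RNAPII in every list, 87.0% did, and of the 114 in both spleen lists and no tumour, 11.4% did. H3K4me3 was gained in this sense at 316 regions, of which 68.7% had Myc in all 3 tumours, against 79.3% of the regions in every list and 1.69% of the 118 lost. H3K27ac was gained at 317 regions (37.5% with Myc), against 75.2% in every list and 1.06% of the 1516 lost. H3K4me1 was gained at 378 regions (14.6% with Myc), against 60.3% in every list, and none of the 802 lost had Myc in all 3 tumours. Counting Myc in any tumour, the shares were 39.5% of gained, 48.2% of lost and 94.0% of constant RNAPII regions, which turned the order of gained and lost, and gained regions had 90.2% for H3K4me3, 78.5% for H3K27ac and 49.7% for H3K4me1. A region had to be called in all of 3 tumours to count as gained, and only 1 library per spleen genotype stood behind RNAPII and H3K27ac.

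Tumours also differed from one another. Of the merged Myc regions, 4645 were found in tumour 1 and in none of the other 6 Myc libraries, 3359 in tumour 2 and 13330 in tumour 3. The private regions of tumour 3 overlapped H3K4me1 of tumour 3 at 94.5% and its H3K27ac at 79.8%. They overlapped H3K27ac of tumours 1 and 2 at 9.56% and 16.1%. The private regions of tumour 1 lay on its own H3K27ac list at 55.9% and on that of tumour 3 at 21.6%, and those of tumour 2 at 59.4% and 21.5%.

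**Figure D3:**
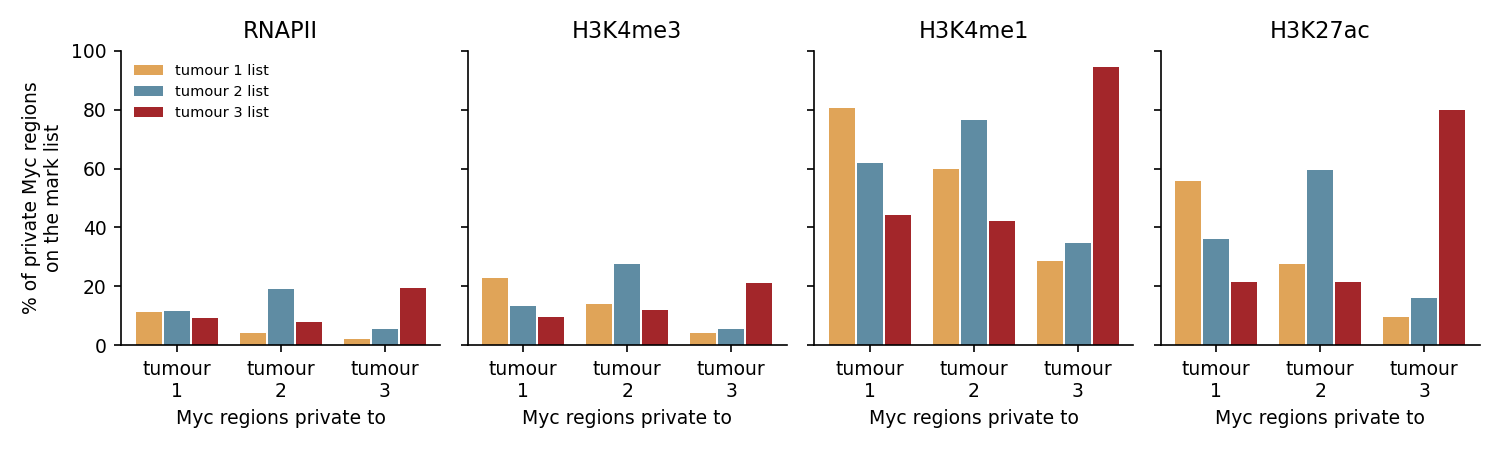
Percent of the Myc regions private to tumours 1, 2 and 3 (n = 4645, 3359 and 13330) that overlapped the RNAPII, H3K4me3, H3K4me1 and H3K27ac peak lists of each tumour. The list with the tumour's own number was the highest in 11 of 12 combinations, the exception being RNAPII for tumour 1 (11.4% against 11.8% in the tumour 2 list).

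Peaks private to tumour 1 were crowded on chromosome 3 and those private to tumour 2 on chromosome 5, the only 2 chromosomes compared. Of the peaks found in tumour 1 and in no other Eµ-myc list of the same antibody, chromosome 3 held 20.2% for RNAPII, 12.3% for H3K4me3, 12.5% for H3K4me1 and 21.4% for H3K27ac. In tumours 2 and 3 chromosome 3 held 1.83% to 5.09%. In tumour 2, chromosome 5 held 13.5%, 11.5%, 10.9% and 12.5% of private peaks for the same antibodies, against 3.30% to 7.23% in tumours 1 and 3. Of all peaks of these lists, chromosome 3 held 5.89% to 7.84% in tumour 1, and chromosome 5 held 6.67% to 8.89% in tumour 2. In tumour 3, chromosome 3 held 3.81% to 5.09% of private and 4.34% to 4.97% of all peaks.

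**Figure D4:**
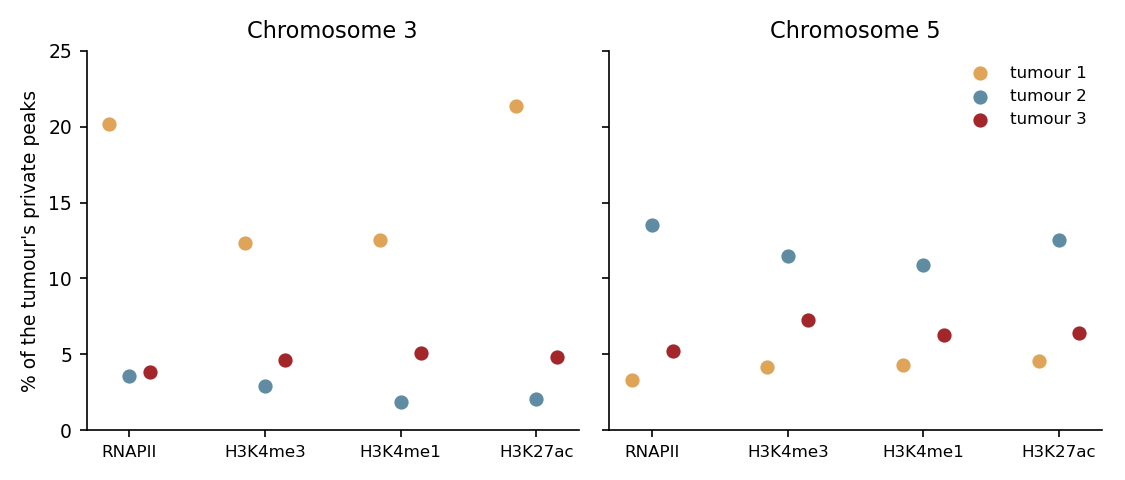
Percent of each tumour's private peaks that lay on chromosome 3 (left) and chromosome 5 (right), by antibody, with 1 point per tumour library. Tumour 1 was the highest on chromosome 3 (12.3% to 21.4%) and tumour 2 on chromosome 5 (10.9% to 13.5%) for all 4 antibodies.

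In 3T9 fibroblasts the comparison was of MycER before and after 4 h of OHT, with 1 library each. Myc peaks numbered 18000 at 0 h and 27693 at 4 h. Of the 0 h peaks, 97.3% (exact 95% interval 97.1 to 97.5) were found at 4 h, and 10873 of the 4 h peaks were new. Retained peaks lay at a median score percentile of 69.1 and new peaks at 22.9. New Myc peaks lay on H3K4me1 of the 0 h cells at 92.8%, on H3K27ac at 75.3%, on H3K4me3 at 25.5% and on RNAPII at 23.8%, and 94.5% lay on at least 1 of them, against 12.6% for shuffled positions. The share of Myc peaks on H3K4me3 was 55.5% at 0 h and 42.5% at 4 h, and the share of H3K4me3 regions with Myc was 67.6% and 86.5%. The change in the first share of -13.0 points became -7.94 with peaks at or above the median score and -0.383 with an equal number of highest-scoring peaks.

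The marks themselves overlapped strongly between 0 h and 4 h of OHT. Of the 0 h peaks, 93.3% for H3K4me3, 93.9% for H3K4me1, 87.6% for H3K27ac and 67.4% for RNAPII were found at 4 h. RNAPII had 7633 peaks at 4 h with none at 0 h, of which 17.9% overlapped a 4 h Myc peak, against 50.9% of the RNAPII peaks present at both times. Myc peaks new at 4 h lay on 6.14% of the new and 8.73% of the kept RNAPII peaks, and on 25.6% of the new and 23.8% of the kept H3K27ac peaks. For H3K4me3 the shares were 12.9% of new and 19.5% of kept peaks, and for H3K4me1 1.79% and 15.0%. The 3 named new Myc peaks, highest-scoring up to ties, were chromosome 10, 38858619 to 38860580, 31547708 to 31549011 and 116170061 to 116173456. The first 2 had H3K27ac at 4 h and no mark at 0 h, and the third had H3K4me1 and H3K27ac at both times. The 3 named shared peaks had all 4 marks at both times. They lay on chromosome 11, 64791939 to 64793556, chromosome 17, 56614721 to 56616813 and chromosome 4, 141100632 to 141103946. All 3 had the same score of 3233.06, the highest in the 4 h list. The new peaks from 31547708 and 116170061 both scored 3100, and 4.48% of the 4 h list scored 3100 or more. Other peaks may share these scores, so the score alone does not single out the tied peaks named here. No replicate was there to test any of the differences between 0 h and 4 h.

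Serum was given to starved fibroblasts to follow Myc at 0, 1 and 2 h, with 1 library each. Myc peaks numbered 5832, 8105 and 16384. Of the 0 h peaks 88.2% (exact 95% interval 87.4 to 89.0) were found at 2 h, and 94.6% of the 1 h peaks were. The 11250 peaks new at 2 h lay on H3K4me1 of the MycER 0 h cells at 95.3%, on H3K27ac at 84.5% and on H3K4me3 at 43.1%. Myc lay on 29.0%, 38.3% and 60.5% of H3K4me3 regions at 0, 1 and 2 h, and the share of Myc peaks on H3K4me3 was 69.9%, 67.3% and 53.6%. The change in that last share from 0 to 2 h was -16.3 points, and it became -7.75 with peaks at or above the median score and turned to 4.41 with an equal number of highest-scoring peaks. The highest-scoring new peaks were chromosome 8, 96694742 to 96699639, chromosome 19, 5447078 to 5449646 and chromosome 10, 80218346 to 80222531. The highest-scoring shared peaks were chromosome 13, 51940607 to 51946380, chromosome 11, 69483123 to 69486913 and chromosome 6, 87799139 to 87801869. The chromosome 13 peak was no longer present at 0 h when at least 50% of its length had to be overlapped. All 6 lay on H3K4me3, H3K4me1 and H3K27ac of the MycER 0 h cells, and all but the chromosome 8 peak on RNAPII.

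In P493-6 cells Myc was compared between repression by tetracycline (0 h), low Myc (OHT with tetracycline), high Myc (untreated), and 1 h and 24 h after tetracycline was removed, with 1 library each. Myc peaks numbered 791 at 0 h, 8666 at 1 h, 18257 at 24 h, 4309 with low Myc and 26146 with high Myc. Of the low Myc peaks, 94.3% (exact 95% interval 93.6 to 95.01) were found with high Myc, as were 85.1% of the 24 h peaks, and 87.5% of the 1 h peaks were found at 24 h. Myc lay on 1.32% of H3K4me3 regions at 0 h, 21.2% at 1 h, 38.1% at 24 h, 9.93% with low Myc and 48.5% with high Myc. RNAPII peaks numbered 13026 at 0 h and 24613 at 24 h. The share of low Myc peaks found with high Myc was 54.1% with an equal number of highest-scoring peaks from each of the 5 lists. That number was 791, the length of the 0 h list, out of 4309 low Myc and 26146 high Myc peaks.

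Myc peaks of P493-6 cells lay mostly on marks of the 24 h cells. H3K4me3 was under 53.6% of the peaks at 0 h, 84.2% at 1 h, 79.0% at 24 h, 76.7% with low Myc and 70.2% with high Myc. H3K27ac was under 49.2%, 92.2%, 91.9%, 86.5% and 85.4%. The difference in H3K4me3 share between 24 h and 0 h was 25.3 points, and between high and low Myc it was -6.50 points. With the 791 highest-scoring peaks of each list these became 41.3 and 12.9 points, and with peaks at or above the median score the second became -0.217. The highest-scoring peaks with high Myc that were absent at 0 h were chromosome 2, 47210127 to 47213485 and 206549362 to 206551691, and chromosome 3, 99535888 to 99537264. The highest-scoring peaks also present at 0 h were chromosome 16, 88847411 to 88848982, chromosome 9, 95055520 to 95056834 and chromosome 3, 135914178 to 135916220. With at least 50% of the length overlapped none of these 3 was present at 0 h, and with peaks at or above the median score only the chromosome 16 peak was. All 6 lay on H3K4me3, H3K27ac and RNAPII of the 24 h cells.

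**Figure D5:**
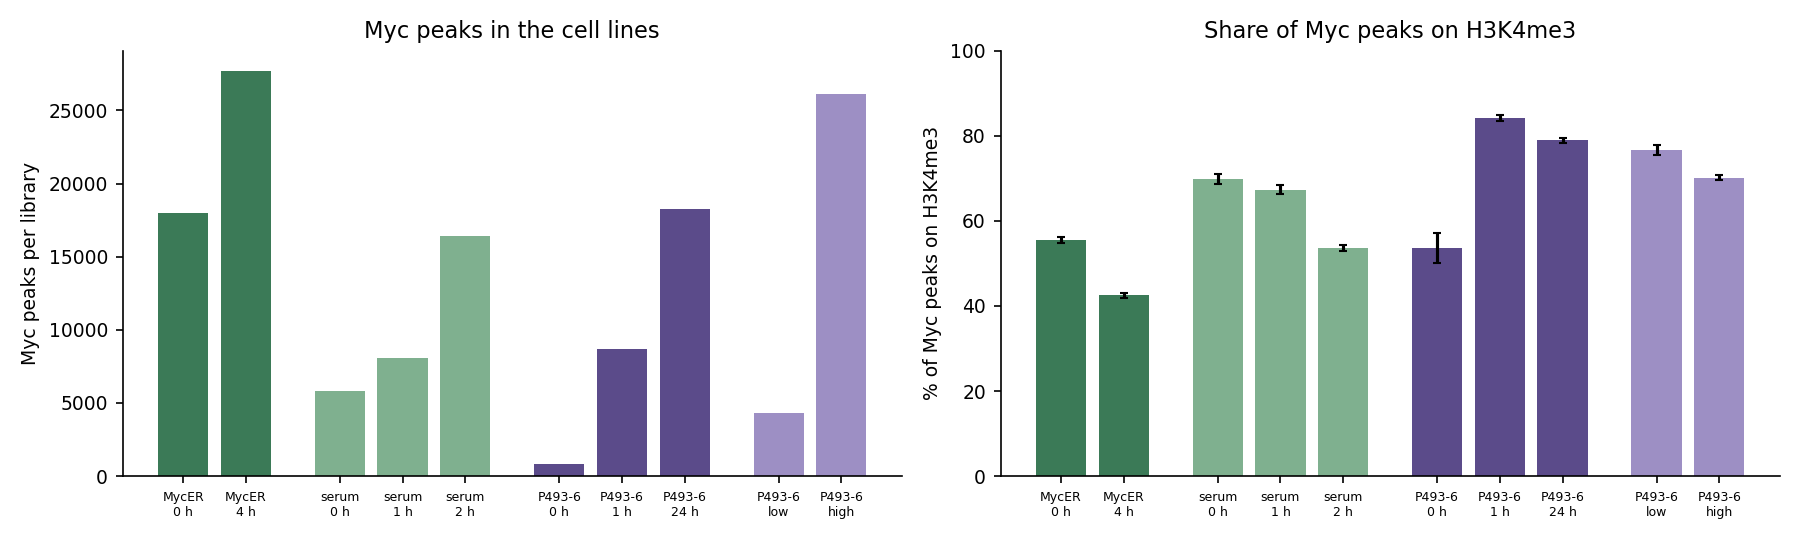
Number of Myc peaks per library (left) and percent of them on H3K4me3 (right) in 3T9 fibroblasts with MycER or serum and in P493-6 cells, with 1 library per bar. Error bars on the right are exact 95% binomial intervals, and the numbers run from 791 in repressed P493-6 cells to 27693 in 3T9 cells with MycER at 4 h.

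Myc sites were also compared between fibroblasts and tumours. Of the 3T9 Myc peaks at 4 h of OHT, 36.2% overlapped a region bound in all 3 tumours, against 2.77% for shuffled positions. Fibroblast peaks on H3K4me3 of the 0 h cells did so at 71.5% (exact 95% interval 70.7 to 72.3) and those off H3K4me3 at 8.27% (7.84 to 8.71). At serum 2 h the shares were 45.7% for all peaks, 78.4% on H3K4me3 and 8.06% off it. Of the 15654 Myc regions bound in all 3 tumours, 61.1% had a 3T9 peak at 4 h of OHT, with 69.1% of those on tumour H3K4me3 and 23.2% of the rest. With an equal number of highest-scoring peaks the on minus off difference of 63.3 points at 4 h of OHT was 41.0.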

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

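Of the tests in this part, those of extra chromosome copies, of a longer tail of weak peaks and of fibroblasts were set before their values were seen, and all others, including the bound for the numbering of the tumours, were chosen or reworded only after the result was seen.

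One result stood out because single libraries of 2 cell lines moved in opposite directions. The share of Myc peaks on H3K4me3 was higher by 25.3 points in P493-6 cells at 24 h than at 0 h, and in 3T9 cells with MycER it changed by -13.0 points from 0 h to 4 h, a difference between models that was not tested. With equal numbers of highest-scoring peaks the P493-6 change was 41.3 points and the MycER change -0.383, and within P493-6 the share was 84.2% at 1 h and 79.0% at 24 h. From low to high Myc in P493-6 the share changed by -6.50 points, the direction of the 3T9 cells, and by 12.9 with equal numbers. The 0 h P493-6 list held only 791 peaks. P493-6 shares were taken on H3K4me3 of the 24 h cells and MycER shares on that of each time, so the measures differ.

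Wild-type spleen library 1 and transgenic spleen library 1 held narrow Myc peaks off every mark list of the Eµ-myc model, at 10.0% and 11.0% of their peaks with medians of 89 and 83 bp, against 0.267% and 0.916% in transgenic spleen libraries 2 and 3. Random calls were argued against, since 534 of the 697 such peaks of wild-type 1 overlapped such a peak of transgenic 1, and the highest of 100 shuffles gave 2. Myc binding that the wide-peak libraries also sampled was argued against as well, since the percent of these peaks of transgenic 1 found in transgenic 3 minus the percent found in wild-type 1 was -36.2 points. The percent of these wild-type peaks found in transgenic 1 exceeded the highest of the other 5 lists by 73.6 points, which any source shared by the pair would give, so a shared batch stays open and is not singled out by it. The labels name no batch, and no other biological explanation was tested.

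Myc peaks off every mark list were crowded on chromosome 3 in tumour 1 (16.0%, against 4.22% and 3.70% in tumours 2 and 3) and on chromosome 5 in tumour 2 (13.7%, against 5.07% and 7.58%). A single local cluster on chromosome 3 of tumour 1 was argued against, since the fullest window of 5 Mb held 15.6% of these chromosome 3 peaks. Chromosome 5 of tumour 2 was not examined in windows, so a local cluster there stays open. Extra copies of chromosome 3 in tumour 1 and of chromosome 5 in tumour 2 may account for the crowding, since each tumour had the highest share of private peaks on that chromosome for 4 of 4 other antibodies in both cases. Copy number itself was not measured, so this remains a hypothesis.

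Tumour 3 had 13330 Myc regions found in no other Myc library of the model, against 4645 and 3359 in tumours 1 and 2. Regions private to tumour 1 lay on its own H3K27ac more often than on that of tumour 3 by 34.3 points. This decides nothing about larger mark lists in tumour 3, since regions chosen as private to a tumour may favour its own marks. Of the 10000 highest-scoring peaks of tumour 3, 3481 overlapped none of the 10000 highest of tumours 1 and 2. That was 2.45 times the mean of the same counts for tumours 1 and 2, so tumour 3 differed most among strong peaks too. Such peaks can still lie in the full lists of the other libraries. A longer tail of weak peaks behind the 13330 regions therefore stays open. Fibroblasts like 3T9 cells were argued against as the source of most of these regions. Of the tumour 3 regions 13.6% lay on 3T9 H3K27ac, a difference of -1.90 points from the higher of tumours 1 and 2. Numbers given without regard to the tumour were argued against by 11 of 12 own-number lists being the highest (permutation p = 0.00154 over 1296 permutations). A difference between the tumours in which enhancers are active may explain these regions, as a hypothesis that came from these same data and was not itself tested. Fibroblasts behind a part of the regions, fibroblasts unlike the cultured 3T9 cells and other cell types in the unpurified lymph node cells stay open, since they were not tested.

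The number of Myc regions in all 3 tumours and in none of the 3 transgenic spleen libraries was 4292, and the highest of the other splits of the 6 libraries gave 867. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The real split also sets the 3 longest lists (27347 to 34142 peaks) against the 3 shortest (5246 to 12985), which favours a high count. The comparison of splits therefore cannot tell stage from list length. With equal numbers of highest-scoring peaks 66 regions were in all 3 tumours and in none of the 4 spleen libraries.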

How the results depend on the processing

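Peaks set to 500 bp, leaving out the 2 narrow-peak Myc libraries, and all alternatives for RNAPII, H3K27ac, the wild-type marks at tumour-only regions and the sharing between fibroblasts and tumours were chosen after seeing the data. Equal numbers of highest-scoring peaks reversed the difference in the share of Myc peaks on H3K4me3 between tumours and transgenic spleen (13.0 points), that in the Myc-bound share of H3K4me3 regions (-3.57), and the changes in H3K4me3 share in serum (4.41) and between high and low Myc (12.9). The Eµ-myc lists, and the 3T9 list set against them, were cut to 5246 peaks each. The cut was to 18000 peaks with MycER, 5832 with serum and 791 in P493-6. It caps the bound share, and tumours had more H3K4me3 regions than transgenic spleen (26252 against 17701), so the reversal to -3.57 decides nothing. Equal numbers also gave 63.6% for transgenic spleen peaks in tumours, 66 tumour-only regions with 95.5% on wild-type marks, 86.7% retained with MycER, 62.9% with serum, 54.1% of low Myc peaks with high Myc and 35.5% of 3T9 peaks in tumours. The filter at the median score gave 2242 tumour-only regions (92.5% on wild-type marks), 96.9% with MycER, 86.1% with serum, 92.7% of low Myc peaks and 41.8% of 3T9 peaks. Peaks of 500 bp gave 71.9% for spleen peaks in tumours, 84.1% with MycER, 81.0% with serum, 89.2% of low Myc peaks and 29.6% of 3T9 peaks. An overlap of 50% gave 91.3% of tumour-only regions on wild-type marks and 35.2% of 3T9 peaks. With 2 tumours enough there were 10915 regions (81.2% on wild-type marks), and without the narrow-peak libraries 89.9% lay on wild-type marks. RNAPII covered length gave 3.29. The H3K4me3 ratio of 1.16 gave an exact permutation p of 0.0286 from absolute differences, the definition computed first, and 0.0571 by double the smaller tail, which was chosen after the first value was seen, so its side of 0.05 depends on how the 2 sides are counted. Apart from that, the cause of these changes was not tested.

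Leaving out 1 transgenic spleen or tumour library at a time gave ratios of 2.32 to 3.65 for the Myc peak number. The difference was -12.4 to -5.22 points for the share on H3K4me3 and 22.2 to 33.8 for the bound share. Of spleen peaks, 86.9% to 94.0% were found in tumours. There were 4195 to 7911 tumour-only regions, with 83.3% to 89.8% of them on wild-type marks. Here the rule asked for 1 library fewer than in the main count of 4170. That favours a higher count, so this range does not measure stability. Leaving out any 1 spleen or tumour library gave ratios of 1.14 to 1.22 for H3K4me3 and 0.996 to 1.17 for H3K4me1 (reversed without tumour 3). For RNAPII and H3K27ac only tumour libraries were left out, with ratios of 1.71 to 1.82 and 0.896 to 1.04. Those ranges do not show how far the single library of each spleen genotype moves the ratio. Counting the main value of each comparison under every alternative, 91 values moved by less than their spread, interval or limit for counts, or stayed on their side of 0.05, 31 moved further, 3 reversed and 1 passed 0.05. The 91 include the H3K27ac ratios without tumour 1 (1.04) and tumour 2 (1.03), which crossed 1. Among secondary values (the changes in H3K4me3 share in the cell lines, the on minus off difference and single regions), 65 stayed, 19 moved and 2 reversed. With double the smaller tail no test could pass 0.05 in so few libraries, so the side of 0.05 says nothing about stability.

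Same-numbered transgenic spleen and tumour libraries did not deviate together (correlations of -0.0133, -0.111 and -0.116), so the numbers were not taken to pair them. With the replicate number as a block, the values of 3.14, -9.21 and 29.3 stayed as they were by construction and each gave an exact sign-flip permutation p of 0.25, the smallest that 3 pairs permit, so no call changed. No library correlated best with its own number. Gene lists at promoters within 1 or 2 kb of a start site and E-box motifs, near the centre or anywhere in the peak, were not run. The depth of the libraries is unknown, which limits every comparison of peak numbers.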

Other observations

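The values in this part were chosen after the data were seen. In repressed P493-6 cells, 430 of the 791 Myc peaks (54.4%) were found in all 4 other Myc lists of the line. Of the 791, 179 peaks (22.6%) lay on no H3K4me3, H3K27ac or RNAPII peak, and 19 of these (10.6%) were among the 430. Spleen-only Myc regions of the Eµ-myc model, 2176 in number with a median width of 100 bp, overlapped at least 1 wild-type spleen mark at 19.3%, against 8.41% for shuffled positions. The narrow off-mark peaks of wild-type 1 (697) and transgenic spleen 1 (1424) were found in a given tumour list at 2.15% to 3.16%. Such peaks can make up a large part of the spleen-only regions, which was not counted. These regions are therefore not to be read as Myc sites lost in tumours.

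Myc regions found in 1 tumour only overlapped at least 1 wild-type spleen mark at 54.4% and H3K4me3 at 10.6%. Of the mark peaks of the tumours, 78.5%, 77.0% and 69.0% of H3K27ac peaks in tumours 1, 2 and 3 had a Myc peak of any tumour, against 42.1% of H3K27ac peaks with a transgenic spleen Myc peak and 12.2% in wild-type spleen. These shares are not like for like. Tumours and transgenic spleen had the merged Myc peaks of 3 libraries each, and wild-type spleen 1 library of 6978 narrow peaks. At serum 2 h, 88.9% of fibroblast Myc peaks were found with MycER at 4 h of OHT. The 5 peak lists of tumour 1 held 16 peaks on chromosome Y, and those of tumours 2 and 3 held 0.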
